A study of Aspergillus niger with 6 samples.

How the data were processed

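RNA-seq libraries were made from mycelium of 1 engineered Aspergillus niger strain in 2 culture states, with 3 biological replicates of each per the labels. The strain is written RG0095 in the sample titles and GR0095 in another label field, and both are taken here to be the same strain. Its genotype lists a deletion of oahA and entries for pyc, mdhC and a C4T318 construct behind a gpd promoter, and it is the same for all 6 samples. Total RNA went into a stranded mRNA library kit per the labels' protocols.

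The deposited table holds 1 column of raw read counts per sample, whole numbers with no normalization, so the authors' counts entered the tests as they stood. The submitters' processing notes name Trimmomatic, HISAT2, Bowtie2, SAMtools, HTSeq, Cufflinks, StringTie and DESeq, with no versions and no order of use. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes cannot be separated with certainty, and near-identical copies can share reads.

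The table has 10505 gene IDs. Of these, 10489 begin with ANI_1_ and 16 begin with Asnifp. None of them (0) matched a gene ID, locus tag, symbol or synonym among the 14404 genes of the RefSeq table of assembly ASM285v2, and the file itself pairs no ID with a name. Gene names, products and positions are therefore not given. The 30 gene lists fixed before the data were examined (among them central carbon metabolism, transport, translation, secreted enzymes, conidiation and stress) could not be matched and were not tested. The loci of the strain's genotype were not analysed here. The ID is the unit of every statement below.

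The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM normalization and group as the only term. IDs entered if they passed edgeR's filterByExpr with its default minimum count of 10 and minimum total of 15. With groups of 3 it asks for about 10 counts in at least 3 libraries. This kept 8963 IDs and left out 1542. The IDs left out held between 0.0203% and 0.0457% of each library's counts. An ID was called at a Benjamini-Hochberg adjusted p under 0.05, and calls of at least 2-fold were counted separately. Fold changes are fermentation over seed on the log2 scale, and the standard error is the absolute log2 fold change divided by the square root of the quasi-likelihood F. Fitted fold changes of IDs near 0 counts in one group depend on edgeR's prior count, so a ratio of pooled CPM, which is an ID's counts scaled to the library total, with an exact Clopper-Pearson 95% interval, stands beside them. These intervals, and the floor of 3 counts used where a group has none, cover counting error only. Values per library were compared by an exact two-sided permutation test, which with 3 against 3 libraries cannot go below p = 0.1.

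Named IDs followed a rule fixed before the data were examined. It takes the 2 largest rises and the 2 largest falls among called IDs with a mean of at least 10 CPM and no overlap between the groups' libraries, and the 3 most abundant IDs of each group. The rule sets no condition on the call for the most abundant IDs. Here they are printed only where they were not called, which keeps the IDs printed to 2 each way. A called one is described by its rank.

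Library totals ran from 16828913 to 20267348 counts. Replicates within a group were compared with a chi-square test of their counts. The statistic per degree of freedom ran from 11.7 to 80.4, so no pair agreed within sampling noise and every library counted as 1 replicate. On simulated counts built from these libraries' means, sizes and dispersions (8963 IDs, 200 changed), the edgeR test recovered 81% of 2-fold and 97% of 4-fold changes for a simulated fermentation against seed comparison, with 15 false calls among 193. Far fewer IDs were changed there than were called in the data, and rises and falls were equal in number. These rates therefore need not hold for the real comparison.

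The groups share replicate numbers, but no label ties equal numbers to a day or batch. Deviations of same-numbered libraries from their group means correlated across IDs at r = 0.04, 0.03 and 0.05, and they were not treated as pairs. The alternatives were other normalizations (RLE, upper quartile, library totals), other low-count filters, a replicate block, DESeq2 1.42.0, limma-voom (limma 3.58.1), edgeR's glmTreat, removal of the 10 most abundant IDs and leaving out each library in turn.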

Results

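RNA-seq profiles were obtained from mycelium of an Aspergillus niger strain engineered for L-malic acid production. Aspergillus niger is a filamentous fungus used in industrial organic acid fermentation. Spores were first grown for 20 h in seed medium, and the resulting mycelium was moved to fermentation medium and sampled at 72 h. Each state had 3 biological replicates. The seed libraries held 18927803, 20267348 and 17595864 gene counts, and the fermentation libraries 16828913, 17719717 and 17538672. In total 8963 of 10505 gene IDs passed the low-count filter and were tested. Between 8701 and 8949 IDs reached 10 counts in a library. After every library was thinned to the depth of the smallest, the mean was 8830 ± 6.08 IDs in seed and 8797 ± 107 in fermentation (SD, n = 3), and an exact permutation test gave p = 0.7.

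The libraries separated by culture state. Libraries of one state correlated across IDs at r = 0.988 to 0.994 in seed and 0.978 to 0.990 in fermentation (log2 CPM). Libraries of different states correlated at 0.857 to 0.872. The first principal component held 88.0% of the variance and split the states. The second held 5.70% and set fermentation replicate 1 apart from fermentation replicates 2 and 3.

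**Figure D1:**
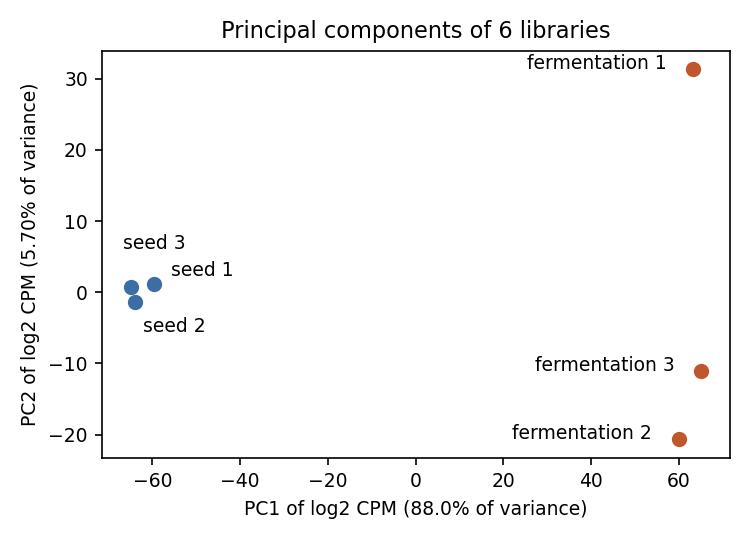
Each point is 1 library, placed on the first (x) and second (y) principal component of log2 CPM over 8963 IDs, with seed in blue and fermentation in orange. The states lie at opposite ends of the first axis, and fermentation replicate 1 lies alone at the top of the second axis.

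The series asks which genes change in mRNA level when the mycelium goes from seed to fermentation culture. Medium and culture time differ together between the states, so their effects cannot be told apart. In fermentation 3036 IDs were higher and 2959 were lower, together 66.9% of those tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 per state). TMM centres the fold changes near 0, so how many rise against how many fall follows from the scaling. Of these calls, 1523 rose and 1311 fell by at least 2-fold, but 1276 and 1655 did under upper-quartile scaling and 1343 and 1520 under library totals alone. A change of at least 4-fold was seen for 508 IDs that rose and 393 that fell, and one of at least 32-fold for 43 that rose and 61 that fell. The median absolute log2 fold change was 0.67, with a median standard error of 0.15. The libraries of the states did not overlap at all for 6497 IDs (72.5%), where chance gives 10%. The count of IDs past a 2-fold change depends on how it is tested: 1683 IDs (920 higher, 763 lower) passed edgeR's glmTreat against a 2-fold change.

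**Figure D2:**
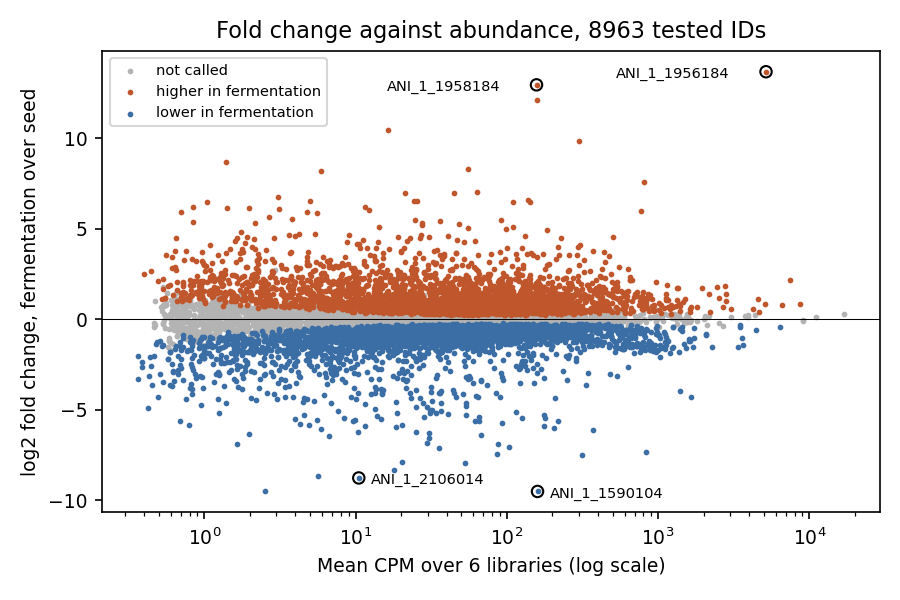
Each point is 1 of the 8963 tested IDs, with its mean CPM over the 6 libraries on a log scale (x) and its log2 fold change of fermentation over seed (y). Orange and blue mark IDs called higher and lower, grey those not called, and circles the 4 IDs with the largest changes by the naming rule, from 13.67 for ANI_1_1956184 to -9.51 for ANI_1_1590104.

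The largest rise was that of ANI_1_1956184, from 0.843 ± 0.0992 CPM in seed to 10338 ± 343 CPM in fermentation (SD, n = 3). Its 48 seed counts stood against 538776 fermentation counts, a ratio of 12238 (95% interval 9230 to 16598). The fitted log2 fold change was 13.67 ± 0.20 (SE, edgeR adjusted p = 6.59e-09). ANI_1_1958184 rose from 2 counts over the 3 seed libraries to 16419 over the 3 fermentation libraries, a ratio of 8951 with a counting interval of 2477 to 73916 (edgeR adjusted p = 4.73e-08). Its fermentation level was 314 ± 72.4 CPM (SD, n = 3). Both were higher in every fermentation library than in any seed library, as the naming rule requires.

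By their ratios the largest falls were smaller than these rises, though the counting intervals of ANI_1_2106014 and ANI_1_1958184 overlapped. ANI_1_1590104 went from 319 ± 55.2 CPM in seed to 0.401 ± 0.190 CPM in fermentation (SD, n = 3), which is 790-fold lower by pooled counts (95% interval 516 to 1276). Its log2 fold change was -9.51 ± 0.27 (SE, edgeR adjusted p = 1.5e-07). ANI_1_2106014 fell from 20.96 ± 4.15 CPM (SD, n = 3), or 1192 counts, to 2 counts over the 3 fermentation libraries, 547-fold lower with a counting interval of 151 to 4519 (edgeR adjusted p = 1.01e-06).

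Of the 10 most abundant IDs of each state, 6 were common to both. The same ID, ANI_1_212154, ranked first in both, at 16074 ± 1606 CPM in seed and 18033 ± 5658 in fermentation (SD, n = 3). It was not called (edgeR log2 fold change 0.29 ± 0.26 SE, adjusted p = 0.336). ANI_1_936024, which ranked 2 in seed and 3 in fermentation, was not called either (0.14 ± 0.22 SE, edgeR adjusted p = 0.579). ANI_1_90014, which ranked 3 in seed and 7 in fermentation, had a log2 fold change of -0.09 ± 0.29 (SE, edgeR adjusted p = 0.802). These IDs were all highest in fermentation replicate 1. Without that library the fold changes were -0.09, -0.14 and -0.55, and ANI_1_90014 was then called lower (edgeR adjusted p = 0.00376). The second most abundant ID in fermentation ranked 26 in seed and rose from 2920 ± 44.7 to 11992 ± 868 CPM (SD, n = 3), a log2 fold change of 2.15 ± 0.14 (SE, edgeR adjusted p = 6.13e-06).

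Of the 100 most abundant IDs of each state, 57 were common to both lists. In the seed list 54 IDs fell, 17 rose and 29 were not called. In the fermentation list 51 rose, 11 fell and 38 were not called. These lists were ranked on the same libraries that were tested, so their direction is not independent evidence. The 10 most abundant IDs of each library took 8.19 ± 0.670% of its counts in seed and 10.03 ± 1.84% in fermentation (SD, n = 3, exact permutation p = 0.2). Fermentation replicate 1 stood highest at 12.1%, and without it the difference fell from 1.84 to 0.80 percentage points.

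Changes of at least 2-fold were spread over the whole range of abundance. IDs were parted into 3 equal classes by their mean over all libraries. In the low class (median 4.46 CPM) 618 rose and 662 fell by at least 2-fold. In the middle class (median 30.9 CPM) the numbers were 401 and 365. In the most abundant class (median 138 CPM) they were 504 and 284. Calls of any size covered 59.0%, 68.6% and 73.1% of the low, middle and high class. The median standard error of a log2 fold change was 0.27, 0.14 and 0.12, so the low class was measured less precisely.

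The changes moved a large part of the mRNA pool. IDs that rose by at least 2-fold held 8.82 ± 0.296% of the counts in seed and 26.2 ± 0.849% in fermentation (SD, n = 3). IDs that fell by at least 2-fold held 22.1 ± 0.457% in seed and 7.001 ± 0.598% in fermentation. Each share had an exact permutation p = 0.1, the smallest that 3 against 3 libraries allow, and the IDs were chosen on these libraries. Which IDs pass depends on the scaling and the libraries. The risen IDs' share of fermentation counts and the fallen IDs' share of seed counts were 21.4% and 26.2% under upper-quartile scaling. They were 22.9% and 24.7% under library totals alone. With 1 library left out, the first ran from 22.8% (without fermentation replicate 1) to 27.0%, and the second from 21.3% to 23.3%.

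**Figure D3:**
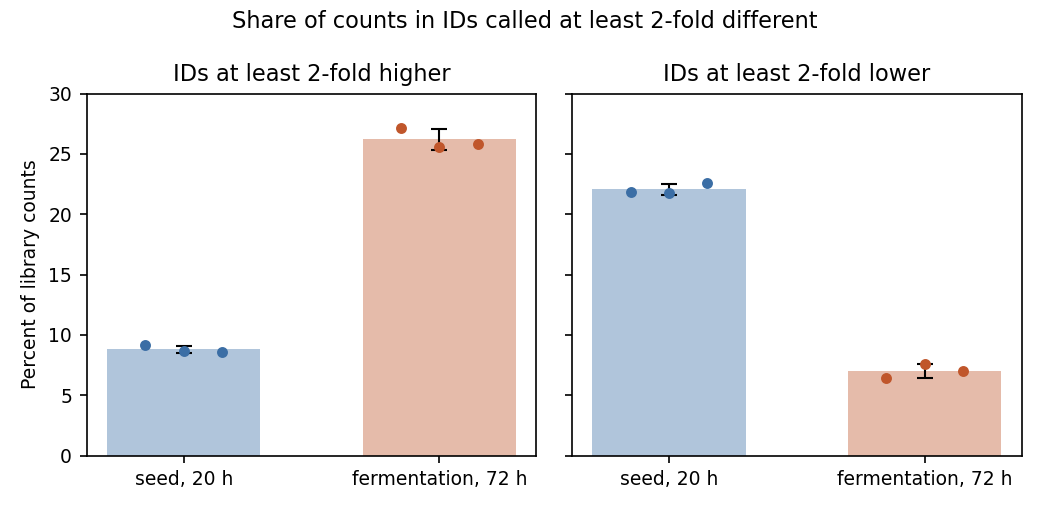
Bars give the mean percent of a library's counts (y) in IDs called at least 2-fold higher (left) or lower (right) in fermentation, points the 3 libraries of each state, and error bars the SD. The left share is 8.82% in seed and 26.2% in fermentation, and the right share is 22.1% and 7.001%.

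Few IDs were counted in 1 state alone. There were 129 IDs with 0 counts in all seed libraries and some in fermentation, of which 19 reached 10 counts summed over the fermentation libraries, a sum that can come from 1 library. Only 1 of the 129 passed the low-count filter and was tested, and it was called. The most counted of them had 146 counts, or 2.80 CPM. Against a floor of 3 counts over the seed libraries (0.0528 CPM), its pooled counts were at least 53.1-fold higher in fermentation. In the other direction 168 IDs were counted in seed alone, of which 14 reached 10 counts summed over the seed libraries and 1 was tested and called. The most counted had 290 counts, or 5.11 CPM, and its pooled counts were at least 88.7-fold lower in fermentation. Neither bound takes account of the spread between libraries. A further 163 IDs had 0 counts in all 6 libraries. An ID with 0 counts was not detectable at this depth, which allows a level of up to 0.0528 CPM over the seed and 0.0576 CPM over the fermentation libraries.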

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

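Which direction had more calls varied with the scaling, filter and libraries used. Counts of calls stayed within 1.5 times the main count except under 2 settings, each explained by its construction. A test against a 2-fold change called 1683 IDs, 920 higher and 763 lower. A filter of at least 10 mean CPM left fewer IDs to test, and 1006 rose and 797 fell by at least 2-fold. Leaving out 1 library at a time gave 5121 to 6105 calls, 2557 to 3068 higher and 2564 to 3037 lower, with 1456 to 1566 and 1275 to 1422 of at least 2-fold. Between 291 (without fermentation replicate 1) and 918 (without seed replicate 2) of the 5995 calls lost significance. Of those lost without fermentation replicate 2, 1 also changed sign. DESeq2 called 6008 IDs, limma-voom 6043 and a fit without a low-count filter 6042. No label says whether same-numbered libraries share more than a number. With a replicate block 5890 IDs were called, and 3 of the 6 libraries correlated best with their own number, which does not exclude pairing. The block changed the call of no named ID. Upper-quartile scaling lowered all log2 fold changes by 0.15 at the median, and the share of calls that were higher went from 50.6% to 42.0%, and to 45.5% under library totals. The 4 IDs with the largest changes kept their direction and call under every alternative that tested them. ANI_1_1956184 was among the 10 most abundant IDs left out. The 3 named IDs that were not called had fold changes whose sign was not stable. That of ANI_1_936024 was -0.012 under upper-quartile scaling. With 1 library left out it ranged from -0.14 without fermentation replicate 1 to 0.27 without fermentation replicate 2, and that of ANI_1_212154 from -0.088 to 0.47 without the same libraries. That of ANI_1_90014 ranged from -0.55 without fermentation replicate 1 to 0.11 without fermentation replicate 2, with 0.04 without fermentation replicate 3. The cause was not tested. The gene list tests and their alternatives were not run, because no ID could be matched to a name. Depth limits the IDs that did not reach about 10 counts in at least 3 libraries, which were not tested. An untested ID can hold more counts in fewer libraries. The leave-one-out values of the top 10 share, and the recomputed shares of counts, were added after the data were seen.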

Other observations

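The tests of directly adjacent IDs, of IDs 3 places apart and of the number of runs, and those without the IDs in runs, were chosen after the pattern was seen. The predictions on similar abundance, on a single library, on the ending and on the splits were written before their results were seen. Some of the large changes came in runs along the ID numbers, 53 of the 901 IDs called with at least a 4-fold change. All but 7 of the ANI_1_ IDs can be read as a number followed by a 3-digit ending, with 18 endings among them. When the tested IDs were ordered by number within an ending, 11 runs of 4 or more successive tested IDs changed by at least 4-fold in one direction, with every member called. Of these, 6 runs with 29 IDs rose and 5 runs with 24 IDs fell. In 5 of the 11 runs at least 1 number within the run was missing among the tested IDs, with up to 4 missing in a run. The largest holds 7 IDs, among them both named rises, ANI_1_1956184 and ANI_1_1958184. It went from 0.000579 ± 8.75e-05% of counts in seed to 1.20 ± 0.0461% in fermentation (SD, n = 3), with log2 fold changes from 3.37 to 13.67. Most of its fermentation share was ANI_1_1956184 alone, at a mean of 10338 CPM. A falling run, also of 7 IDs, includes ANI_1_1590104 and went from 0.0733 ± 0.0125% to 0.000954 ± 7.79e-05% of counts, with log2 fold changes from -2.07 to -9.51. In the other rising runs log2 fold changes ran from 2.08 to 6.99, and the other falling runs reached -7.97.

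Adjacent IDs were also alike outside these runs. Across genes, which are not independent replicates, the log2 fold changes of adjacent IDs correlated at r = 0.237, against at most 0.0352 in 1000 shuffles of the order within an ending. The correlation was 0.107 at 2 places apart and 0.0622 at 3 places, and at 20 places it was -0.00366. With the 53 run IDs left out it was 0.175 for adjacent IDs and 0.0495 at 2 places, with shuffles up to 0.0343 and 0.0360. Shuffled orders gave at most 3 runs where the data had 11, but their longest run held 6 IDs against 7 in the data. If the ID numbers follow genome order, the 0.0622 at 3 places argues against reads shared between directly adjacent gene models alone. Its shuffles reached 0.0379. Outside the runs such shared reads stay open, since r at 3 places was then 0.0203, with shuffles up to 0.0341. The run IDs were picked for changing alike, so leaving them out tends to lower r, and the shuffles did not repeat that choice. The fall from 0.0622 therefore cannot place the likeness in the runs alone. Adjacent IDs were alike in abundance as well, with r = 0.346 for mean log2 CPM. Such abundance is argued against as the source of the alike fold changes, since shuffles within 10 abundance classes reached only 0.0324. Leaving out any 1 library gave at least 0.231 for the fold changes of adjacent IDs, so no single library carries their likeness. Copies of a gene with near-identical sequence, which could share reads over several places, remain open and were not tested for want of sequences. A candidate explanation, also open and not tested for want of gene positions, is that the numbers follow genome order and that neighbouring genes change together with the culture state, as members of a gene cluster would. The file does not state what the numbers mean.

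The share of calls that were higher ran from 41.3% (43 of 104) to 61.5% (24 of 39) over the 18 endings. A chi-square test against 1000 circular shifts of the ordered calls, which keep neighbours together, gave p = 0.24, so chance placement was not excluded. Differences between a library and the other 2 of its state were also alike between adjacent IDs, with r from 0.0371 in seed replicate 2 to 0.105 in fermentation replicate 2. Each lay above the highest of its own 1000 shuffles, by the least in seed replicate 2 (0.0319), a test added after these values were seen.

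The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 5995 calls and was the only 1 with as many, and the highest of the other splits gave 0. Each of the other splits puts libraries of both states in both groups, so the state difference enters the spread within groups. That lowers their calls by construction, so these counts cannot decide whether the real calls arose by chance.

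Fermentation replicate 1 lay farthest from its group. The SD over IDs of its log2 difference from the mean of the other 2 was 0.50, against 0.41 and 0.35 for fermentation replicates 2 and 3 and 0.25 to 0.35 for the seed libraries. Its TMM factor was 0.879, and those of the other libraries were 0.989 to 1.05. None of the 16 IDs beginning with Asnifp passed the low-count filter. They held 1, 5 and 45 counts in seed replicates 1 to 3 and 10, 6 and 25 counts in fermentation replicates 1 to 3.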
